A study of Mus musculus with 24 samples.

How the data were processed

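The data are bulk RNA sequencing of mouse brain, 24 libraries from polyadenylated RNA. Per the labels, RNA was extracted with TRIzol and sequenced on an Illumina NovaSeq. The authors aligned reads with HISAT2 2.1.0 to mm39 and counted them per gene with featureCounts 2.0.6; the annotation and the strand setting are not stated. The deposited values are raw counts per gene symbol with no normalization, in 1 table of 40836 genes and 24 columns. Columns are headed by numbers, and each library was joined to its column by the number given in its label. Among counts from 1 to 19, between 62.6% and 70.8% per library were even, so many read pairs were counted as 2 reads, and the counts overstate the number of fragments.

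Total counts ran from 37.4 M to 99.5 M per library. Genes were kept by edgeR's filterByExpr over the 6 groups, which left 20437. The fit used R 4.3.3 and edgeR 4.0.16, with TMM factors, 1 coefficient for each of the 6 groups (E code by time code), and quasi-likelihood F tests with 18 residual degrees of freedom; genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Comparisons were E4 minus E3 at each time code and averaged, the differences between time codes averaged over E codes, time code 15 minus 05 within each E code, and the interaction. Another comparison was of titled months within a time code in a fit with months and an E4 minus E3 term per time code. The library numbers were not used as a block: the correlation of libraries that share a number (median -0.164 over 60 pairs, after removing group means) was below that of libraries with different numbers (median 0.152 over 180 pairs). Differences in brain region between libraries were not removed first, so both medians also reflect how the regions lie over the numbers. They cannot show whether a shared number marks a pair. On simulated data with the per-gene spread of this fit, 4 against 4 libraries recovered 47% of 100 genes changed 2-fold and 68% of 100 changed 4-fold, with 8 false calls. The simulated genes were drawn independently, each around 1 mean for all libraries outside the change. Differences in brain region or between sets of columns were not simulated, so the shares recovered in the real data may differ.

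Of 40 gene lists of pathways, cell types and brain regions written before the data were examined, 39 could be tested; the mitochondrially encoded list could not, since 0 of its 13 genes are in the table. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation, and with fry, as 1 family of 39 lists per comparison. Members were also adjusted over the list alone. The list tests were run for 7 comparisons (the 4 of E4 minus E3 and the 3 of time codes averaged over E codes), a restriction made after the data were seen. Named genes were chosen by a rule set before the data were examined. It takes the 8 higher and 8 lower genes with the largest change past the threshold, or the 4 with the smallest p where fewer than 4 passed. It adds 10 genes tied to the series title, up to 4 members with the smallest p of a list, and 5 genes for the sex check. Other genes named with the calls of DESeq2, with list-alone calls beyond 4 per list, or with library differences were chosen after their values were seen.

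Alternatives set in advance were RLE and upper-quartile factors, no filter, a stricter filter (1 CPM in 8 libraries), mitochondrial genes left out, DESeq2 1.42.0, limma-voom, a replicate block, titled month as a covariate, only the libraries compared, stricter thresholds, and leaving out each library. Added after the data were seen were a term for the 8 libraries with a cerebellum and hindbrain mean above 4 log2 CPM, leaving these 8 out, a fit with this term and a term for each set of 3 adjacent column numbers (E4 against E3 and the interaction only), leaving out the 3 libraries with Hbb-bs above 100 CPM, and leaving out the 2 with Gh above 1000 CPM. No sex covariate was fitted, since all 24 libraries had the male pattern. Genome positions are not given, because the annotation at hand is of another build.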

Results

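The 24 libraries measured polyadenylated RNA from mouse brain. Their names give an E code (E3 or E4), a time code (05, 10 or 15) and a number, which makes 6 groups of 4 libraries. Their titles name 6 months with 4 libraries each. The labels spell out neither code. The series title concerns ApoE4, microglial lipids, Asxl1, the liver X receptor alpha (Nr1h3) and methylation of histone H3 at lysine K4, so the difference between E4 and E3 was taken as the main question. Total counts ran from 37.4 M to 99.5 M per library (M, mega), with a median of 48.8 M. The titles call the libraries biological replicates, but nothing in the labels says that they came from separate animals, so the p-values measure the spread between these samples. Libraries are named by group and number, as in E3-05 2, and genes by the symbol in the count table, which gives no positions. All differences are log2 fold changes with their standard error (SE), from fits to 4 libraries per group.

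The largest difference among the libraries was one of brain region, and it ran across the labelled groups. The list of 12 cerebellum and hindbrain genes averaged 6.62 to 7.83 log2 CPM in 8 libraries and -0.49 to 1.90 in the other 16. CPM are counts scaled to the library total times its TMM factor. Gabra6, a receptor subunit of cerebellar granule cells, was at 85.9 to 536 CPM in those 8 and at 0 to 4.59 CPM in the others. Drd1, a dopamine receptor of striatal neurons, was at 0.818 to 2.55 CPM against 10.5 to 116 CPM. The 14 homeostatic microglia genes averaged 3.38 to 3.93 log2 CPM in the 8 libraries and 4.25 to 4.87 in the other 16. E3-05, E4-05, E4-10 and E3-15 held 1 of the 8 hindbrain libraries each, and E3-10 and E4-15 held 2 each. The first principal component carried 51.1% of the variance, with scores from 67.3 to 107 in the 8 and from -69.0 to -7.86 in the others.

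Smaller sets of libraries carried other tissue. Gh, the growth hormone of the pituitary, was at 7107 CPM in E3-05 4 and 6087 CPM in E4-10 2, and at 76.0 CPM or less in the other 22. Hbb-bs, a haemoglobin chain, was at 145 CPM in E3-05 1, 169 CPM in E4-05 1 and 169 CPM in E3-05 2. The 8 hindbrain libraries are those whose column numbers in the count table are multiples of 3. With a term for these 8 libraries in the edgeR fit, 100 genes differed between the 8 sets of 3 adjacent column numbers. Each set holds both E codes, and 6 of the 8 hold 1 time code. Of 100 random divisions, which did not keep time codes together, 1 gave more, with 201. Every comparison is between libraries as labelled, and a count of 0 genes is not read as the absence of an effect. With no differences, about 1022 of the 20437 genes would have an unadjusted p under 0.05 if the tests were exact. The 13 comparisons gave 226 to 774 in edgeR, fewer than that, so these counts are no sign of differences. Differences in brain region stayed in the spread of the 6-group fit (coefficient of variation 40.8%, against 22.5% with a hindbrain term), and genes are not independent. The shortfall therefore does not show that the tests were conservative.

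**Figure D1:**
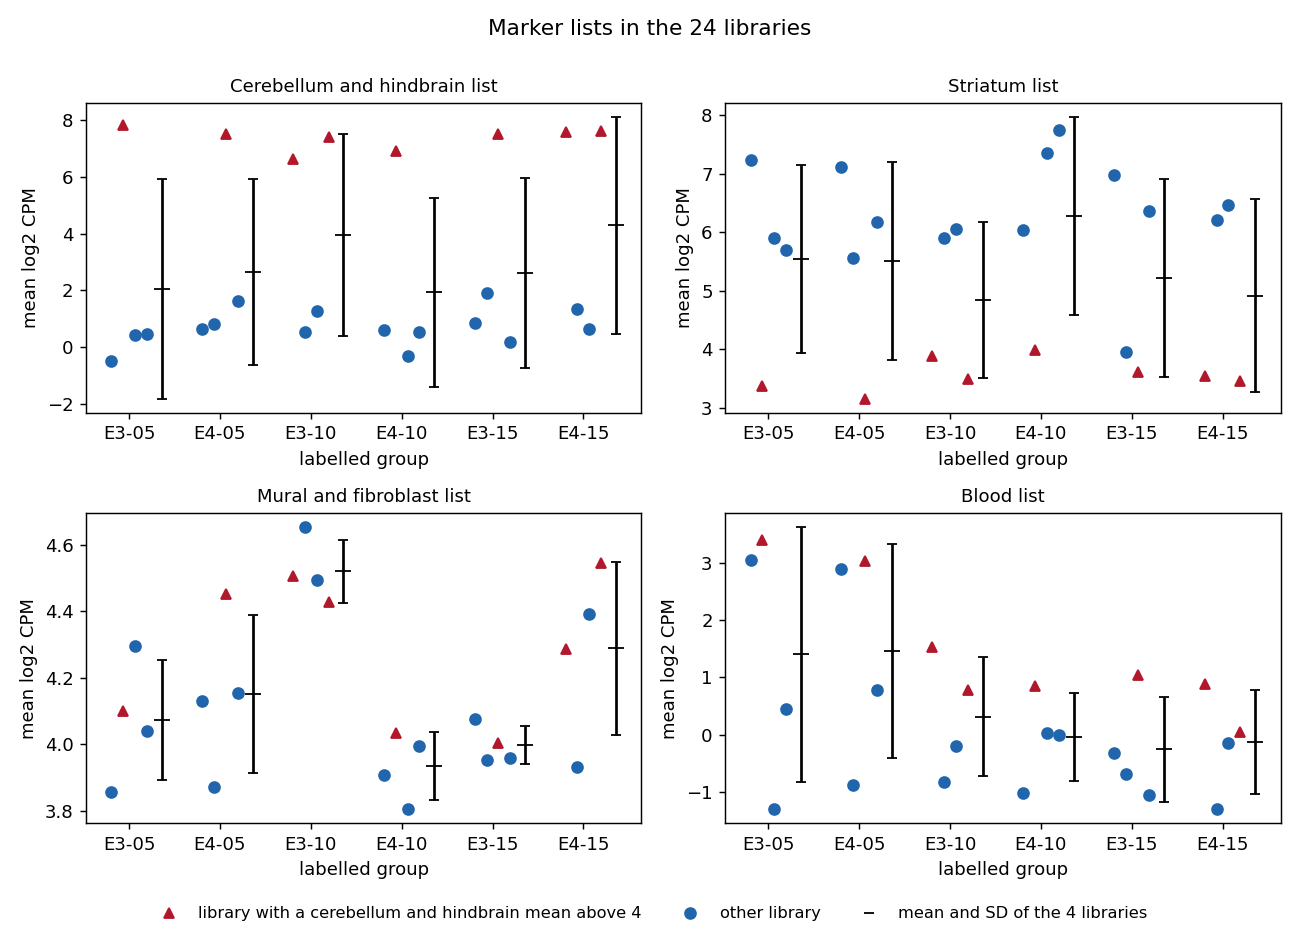
Mean log2 CPM (y axes) of 4 marker lists in each of the 24 libraries, by labelled group (x axes); triangles are the 8 libraries with a cerebellum and hindbrain mean above 4, circles the other 16, and bars the mean and SD of the 4 libraries of a group. Each of the 6 groups holds at least 1 of the 8 hindbrain libraries, and the mural and fibroblast list lies lower in all 4 libraries of E4-10 than in all 4 of E3-10.

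At time code 05, the myelin and oligodendrocyte list lay higher in E4-05 than in E3-05, largely through E4-05 4. All 20 members had positive log2 fold changes with a median of 0.26. They include Cldn11 (0.37, SE 0.29), a tight junction protein of myelin, and Gjc3 (0.36, SE 0.27), a gap junction protein of oligodendrocytes. The list passed limma's camera with a preset correlation (adjusted p = 0.00294), and stood at adjusted p = 0.866 with an estimated correlation. The call ended without E4-05 4 (median 0.06) and without E3-05 1 (0.18), and the median was 0.43 without E4-05 1. The pituitary hormone genes Cga (-7.29, SE 2.38), Pomc (-6.51, SE 1.83), Gh (-6.29, SE 2.43) and Prl (-6.07, SE 2.25) fell. Of the 10 hypothalamus and pituitary genes these 4 passed in edgeR when adjusted over the list alone and 0 over all genes. These 4 calls ended without E3-05 4, the library with 7107 CPM of Gh, and also without E4-05 1, E4-05 2 or E4-05 4, and the list's median (0.19) and mean (-2.37) differ in sign. Each group held 1 hindbrain library, but this does not balance the other regions. Of the 16 libraries that were not hindbrain, E4-05 4 had the highest mean of the thalamus list (6.83 log2 CPM) and of the myelin list (7.88). Whether its region accounts for the myelin genes was not tested. Over all 20437 genes tested, edgeR called 0, with 263 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each.

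At time code 10, genes of vessel walls and meningeal fibroblasts were lower in E4-10 than in E3-10. The mural and fibroblast list averaged 3.93 ± 0.10 log2 CPM in E4-10 and 4.52 ± 0.10 in E3-10 (SD, n = 4 each), without overlap. The other 4 groups averaged 4.00 to 4.29, so E3-10 was the highest of the 6 groups and E4-10 the lowest. A two-sided exact permutation test, added after the values were seen, gave p = 0.0286, the smallest that 4 against 4 libraries can give. Of its 14 measured members 13 had negative log2 fold changes, with a median of -0.73, and 8 were lower in E4-10 when adjusted over the list alone in edgeR. Over all genes edgeR called 0 of them and DESeq2 called Slc6a13 (adjusted p = 0.011). Among them were the fibrillar collagens Col3a1 (-0.99, SE 0.33) and Col1a2 (-0.71, SE 0.28), and Acta2 (-1.06, SE 0.27) and Myh11 (-0.92, SE 0.22) of the contractile apparatus of smooth muscle. The other 4 were the growth factor Igf2 (-1.04, SE 0.25), the proteoglycan Lum (-0.94, SE 0.25), the GABA transporter Slc6a13 (-0.92, SE 0.19) and vitronectin, Vtn (-0.40, SE 0.09). The list passed camera with the preset correlation (adjusted p = 2.26e-14) and with an estimated one (adjusted p = 0.0098), and also fry (adjusted p = 0.00286), which tests whether the genes move one way on balance. The call of the list held without each of the 8 libraries in turn, as did those of 7 of the 8 genes; that of Col1a2 ended without any of 6 libraries, all but E4-10 2 and E3-10 3. E3-10 held 2 hindbrain libraries and E4-10 held 1; the median was -0.66 with a term for them. With terms for the sets of adjacent columns and for the hindbrain libraries, added after the data were seen, the list passed with the preset correlation (adjusted p = 5.24e-13) but not with an estimated one (adjusted p = 0.0749).

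The 4 genes with the smallest p at time code 10 were also lower in E4-10 than in E3-10. They were Lmod1, a leiomodin of smooth muscle (-1.06, SE 0.19), the bone morphogenetic protein Bmp6 (-0.82, SE 0.15), vinculin, Vcl (-0.32, SE 0.06), and the amino acid transporter Slc6a20a (-0.81, SE 0.16). For all 4, E3-10 stood farther from the other groups than E4-10 did. Mean CPM was 6.54 in E3-10, 3.10 in E4-10 and 3.43 to 4.48 in the other 4 groups for Lmod1, and 26.0, 14.6 and 15.5 to 21.8 for Bmp6. It was 61.9, 49.2 and 50.4 to 53.4 for Vcl, and 28.7, 16.2 and 19.4 to 23.5 for Slc6a20a. edgeR called 0 of the 20437 genes (smallest adjusted p = 0.22), with 655 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 14, all lower in E4-10, these 4 among them with adjusted p between 6.84e-05 and 0.00383. With the term for hindbrain libraries, edgeR called Lmod1 (-1.13, SE 0.16) and the ferroxidase Cp (-0.60, SE 0.10), a setting added after the data were seen.

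Several glial and immune lists at time code 10 passed camera only with the preset correlation, and in these lists 0 members passed in edgeR adjusted over the list alone or over all genes. The astrocyte list had 15 of 16 members below 0 (median -0.22; adjusted p = 0.367 with an estimated correlation). Reactive astrocyte genes had 12 of 14 below 0 (median -0.34; adjusted p = 0.358 with an estimated correlation), with Gfap at -0.82 (SE 0.35), and myelin genes 20 of 20 (median -0.33; adjusted p = 0.716 with an estimated correlation). The interferon response list had 24 of 26 members below 0 (median -0.17; adjusted p = 0.406 with an estimated correlation) and antigen presentation 15 of 17 (median -0.21; adjusted p = 0.582 with an estimated correlation). Genes of disease-associated microglia had 20 of 25 below 0 (median -0.18; adjusted p = 0.358 with an estimated correlation), with Gpnmb at -0.57 (SE 0.23) and the growth factor Igf1 at -0.46 (SE 0.20). Fatty acid and lipid droplet genes had 20 of 26 below 0 (median -0.15; adjusted p = 0.367 with an estimated correlation), with the lipid droplet coat proteins Plin4 at -0.93 (SE 0.31) and Plin3 at -0.65 (SE 0.30). Endothelial genes had 14 of 15 below 0 (median -0.14; adjusted p = 0.468 with an estimated correlation), and nuclear genes of oxidative phosphorylation 17 of 20 (median -0.09; adjusted p = 0.554 with an estimated correlation). Without E3-10 1, a hindbrain library, all of these calls ended but those of the 2 astrocyte lists. The medians were then -0.04 for myelin, -0.02 for oxidative phosphorylation, -0.07 for endothelial genes, -0.09 for fatty acid genes and -0.10 for disease-associated microglia. Calls also ended without E3-10 2 (disease-associated microglia at -0.06, antigen presentation, endothelial, oxidative phosphorylation), E4-10 2 (disease-associated microglia) and E4-10 3 (antigen presentation, myelin). Without E4-10 4 they ended for interferon (-0.09), antigen presentation (-0.10) and oxidative phosphorylation. Other medians that moved by over 1.5 times were -0.60 for reactive astrocytes, -0.28 for interferon and -0.35 for antigen presentation without E4-10 2, -0.11 for disease-associated microglia without E4-10 1, and -0.22 for endothelial genes without E3-10 4. E3-10 held 2 hindbrain libraries and E4-10 held 1. The astrocyte list averaged 7.92 to 8.24 log2 CPM in the 8 hindbrain libraries and 7.44 to 7.91 elsewhere. Reactive astrocyte genes averaged 2.48 to 3.16 and 2.06 to 2.65. This share by itself tends to put both lists lower in E4-10. Outside the hindbrain libraries both were still lower in E4-10 than in E3-10, at 7.60 to 7.82 against 7.88 and 7.90, and 2.06 to 2.13 against 2.57 and 2.62.

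Homeostatic microglia genes lay above 0 in E4-10 against E3-10 for 14 of 14 members (median 0.40; adjusted p = 0.716 with an estimated correlation), among them Cd33 (0.51, SE 0.35) and Gpr34 (0.47, SE 0.39). E3-10 held 2 hindbrain libraries and E4-10 held 1, and this list averaged 3.38 to 3.93 log2 CPM in the 8 hindbrain libraries and 4.25 to 4.87 elsewhere. The unequal share by itself puts the list mean higher in E4-10, and that of the cerebellum and hindbrain list lower. Among the hindbrain libraries the microglia list lay at 3.61 in E4-10 2, 3.93 in E3-10 1 and 3.40 in E3-10 4. Region lists moved beside the microglia genes. Striatal genes had 11 of 11 members above 0 (median 1.49; adjusted p = 0.53 with an estimated correlation), GABAergic neuron genes 9 of 13 (median 0.48; adjusted p = 0.367 with an estimated correlation), and hypothalamus and pituitary genes 9 of 10 (median 4.77; adjusted p = 0.397 with an estimated correlation). Choroid plexus genes had 13 of 13 members below 0 (median -1.50; adjusted p = 0.367 with an estimated correlation) and cerebellum and hindbrain genes 12 of 12 (median -1.21; adjusted p = 0.752 with an estimated correlation). The striatal and choroid plexus calls held without each of the 8 libraries in turn, with a choroid plexus median of -2.39 without E4-10 4. The microglia call ended without E3-10 4 (median 0.21) or E4-10 3 (0.30), and the median was 0.26 without E4-10 4, 0.64 without E3-10 2 or without E4-10 2. The hypothalamus and pituitary call ended without E4-10 2 (1.00), and the GABAergic call without E3-10 1, E4-10 1, E3-10 2, E3-10 3 or E4-10 4. The cerebellum and hindbrain call ended without E3-10 1, E4-10 1, E4-10 3 (-0.81), E4-10 4 or E3-10 4, where the median turned to 0.40, and the median was -7.20 without E4-10 2. The complement list was not called (camera adjusted p = 0.0806).

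At time code 15, the list of Asxl1, polycomb and H3K4 methylation genes had 22 of 28 members above 0 in E4-15 against E3-15 (median 0.11; camera adjusted p = 0.00868 with the preset correlation and 0.942 with an estimated one). Homeostatic microglia genes had 14 of 14 members below 0 (median -0.27), myelin genes 20 of 20 (median -0.19) and pan-neuronal genes 12 of 14 (median -0.22). Below 0 were also cholesterol synthesis genes 17 of 24 (median -0.10) and cytosolic ribosomal protein genes 21 of 24 (median -0.11). Mural and fibroblast genes had 11 of 14 members above 0 (median 0.32), with Col3a1 at 0.88 (SE 0.33), and cerebellum and hindbrain genes 9 of 12 (median 1.47). All 8 lists stood at adjusted p = 0.942 with an estimated correlation, and 0 of their members passed in edgeR adjusted over the list alone or over all genes. Each of the 8 calls ended without at least 2 single libraries. Without E3-15 1 only the neuronal and mural calls remained of the 8, with medians of -0.04 for myelin, -0.02 for ribosomal proteins and -0.16 for microglia. Without E4-15 4 only the myelin call remained, with medians of 0.06 for the Asxl1 list, -0.04 for ribosomal proteins, -0.09 for microglia, -0.05 for cholesterol synthesis, -0.13 for neuronal and 0.91 for hindbrain genes. The microglia, neuronal and hindbrain calls also ended without E4-15 1 (-0.09, -0.10 and 0.81) or E3-15 4 (-0.08, -0.11 and 1.07), and the neuronal and hindbrain calls without E3-15 2. The myelin and cholesterol calls ended without E4-15 2 or E3-15 3 too, the neuronal call without E3-15 3, the mural call without E4-15 3 and the ribosomal call without E3-15 2. Without E3-15 3 medians grew to -0.48 for microglia, 5.70 for hindbrain genes, 0.20 for the Asxl1 list and -0.16 for ribosomal proteins, and that of microglia to -0.44 without E4-15 2 and -0.51 without E4-15 3. E4-15 held 2 hindbrain libraries and E3-15 held 1, and without the 8 hindbrain libraries 0 lists were called. edgeR called 0 genes, with 271 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each. The smallest p was that of Tmprss4, a membrane protease (-4.17, SE 0.87, adjusted p = 0.987). This gene lay near the floor, with 2 counts in total in E4-15 and 43 in E3-15.

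Averaged over the 3 time codes, 15 lists passed camera with the preset correlation in E4 against E3, 2 higher and 13 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.587. The striatal and olfactory bulb lists were higher (medians 0.36 and 0.49). Lower were choroid plexus, mural and fibroblast, reactive astrocyte, myelin, interferon response, glucocorticoid and heat shock, and pan-neuronal genes. Lower by 0.04 or less in the median were cholesterol synthesis, fatty acid and lipid droplet, antigen presentation, lysosome, complement and oxidative phosphorylation genes. Each of the 15 medians moved by over 1.5 times without at least 1 single library. It turned sign for myelin without E3-10 1 (-0.08 to 0.02), for antigen presentation without E3-10 2, and for complement without E3-05 3 or E3-10 2, and moved without 9 of the 24 libraries for reactive astrocytes, 7 for pan-neuronal genes and 5 each for interferon, glucocorticoid and striatal genes. For mural and fibroblast genes it moved without E3-05 3 alone (-0.11 to -0.07). Each of the 15 calls ended without at least 3 of the 24 libraries left out singly. The chemokine Ccl2 (-1.67, SE 0.48) fell when adjusted over the 15 measured cytokine and NF-kB genes alone, a call that ended without any 1 of 14 libraries. Ccl2 lay near the floor, with 4 to 21 counts in total per E4 group of 4 libraries and 30 to 44 per E3 group. Over all genes 0 members of any list passed in edgeR. Choroid plexus genes had 12 of 13 members below 0 (median -0.25; adjusted p = 0.631 with an estimated correlation). Their call ended without E4-05 1 (-0.12), E3-05 2 (-0.06) or E4-10 3 (-0.13), and the median ran up to -0.56, without E4-10 4. Libraries of E3 and of E4 held 4 hindbrain libraries each. edgeR called 0 genes, with 246 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each. With the terms for column sets and hindbrain libraries edgeR called 0 genes too, with 524 at an unadjusted p under 0.05, and at time codes 05, 10 and 15 it called 0 each, with 876, 1179 and 442. Camera then called 3 lists averaged with the preset correlation, against 15 without these terms.

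The genes that the series title points to did not pass in any E4 against E3 comparison in edgeR or DESeq2. Apoe itself differed by -0.04 (SE 0.12) at time code 05, -0.09 (SE 0.12) at 10 and -0.01 (SE 0.12) at 15, and by -0.05 (95% confidence interval -0.19 to 0.10) averaged over time codes. It ran from 819 to 1203 CPM over the 24 libraries. These are counts under the mouse gene symbol after alignment to mm39. They cannot tell alleles apart, and the labels do not say which allele the E codes stand for. Asxl1, a chromatin regulator that acts with polycomb proteins, differed by 0.01 averaged over time codes (interval -0.09 to 0.11). Nr1h3 differed by -0.08 (interval -0.59 to 0.44) and its relative Nr1h2 by -0.11 (interval -0.24 to 0.02). The sterol exporters Abca1 and Abcg1, both targets of these receptors, differed by 0.05 each (intervals -0.10 to 0.20 and -0.09 to 0.20). Trem2, a lipid receptor of microglia, differed by 0.02 (interval -0.45 to 0.49), and Kmt2a, an H3K4 methyltransferase, by -0.06 (interval -0.26 to 0.14). Nr1h3 was at 4.99 to 8.02 CPM in the 8 hindbrain libraries and at 2.26 to 3.76 CPM elsewhere. Trem2 was at 3.58 to 6.87 CPM and 7.49 to 12.0 CPM. Their differences at time codes 10 and 15 alone therefore also carry the unequal numbers of hindbrain libraries. Over the 18 liver X receptor targets camera gave adjusted p = 0.782 at time code 05, 0.0866 at 10, 0.564 at 15 and 0.709 averaged, and 0 of the 18 passed in edgeR adjusted over the list alone or over all genes.

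**Figure D2:**
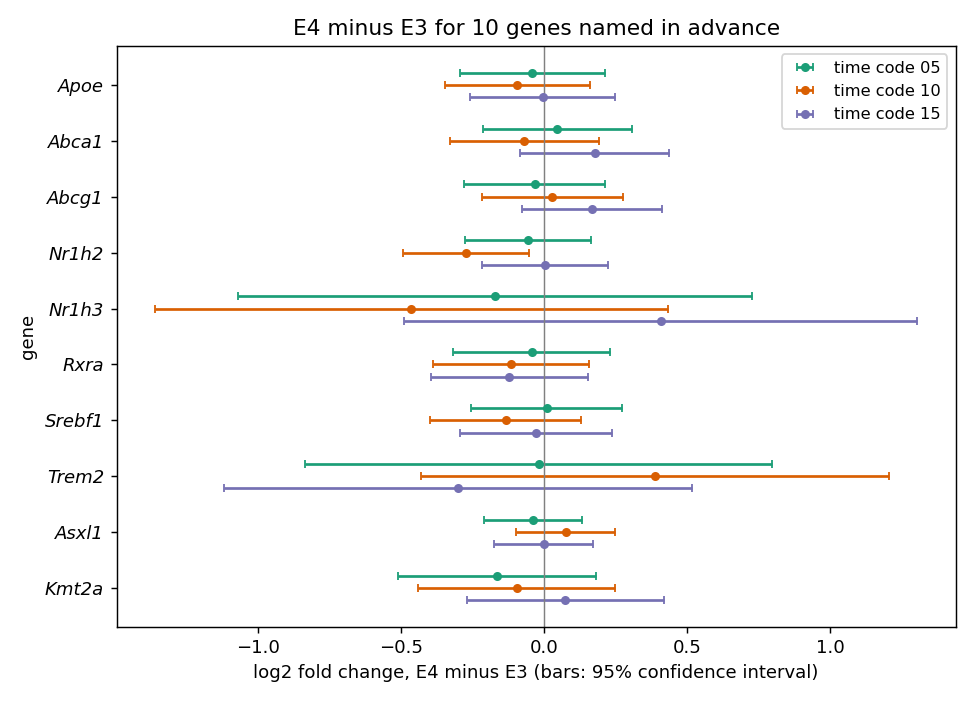
Log2 fold change of E4 minus E3 (x axis) for 10 genes named before the data were examined (y axis) at time codes 05, 10 and 15; points are edgeR estimates from 4 libraries per group and bars are 95% confidence intervals. The interval of Nr1h2 at time code 10 lies below 0 without adjustment (adjusted p = 0.915), and the other 29 include 0. Nr1h3 and Trem2 differ between hindbrain and other libraries, and E3 and E4 hold unequal numbers of hindbrain libraries at time codes 10 and 15.

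Whether the difference between E4 and E3 itself varied among the time codes was tested by the interaction of both codes. Lmod1 and Bmp6 had the smallest p (adjusted p = 0.732 each), followed by the proteoglycan Ogn and by Slc6a13. edgeR and limma-voom called 0 genes, with 377 at an unadjusted p under 0.05 in edgeR, and DESeq2 called 7, which were Lmod1, Bmp6, Ogn, Vcl, Slc6a13, Slc6a20a and Gm7008. Lmod1 passed in edgeR with the term for hindbrain libraries (adjusted p = 0.0295).

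Blood genes were lower at the later time codes. All 7 members of the blood list had negative log2 fold changes in time code 10 against 05 (median -2.49) and in 15 against 05 (median -2.62), averaged over E codes. In both, 5 fell in edgeR when adjusted over the list alone and 0 over all genes. These were the haemoglobin chains Hbb-bs (-3.27, SE 0.75, in 15 against 05), Hba-a1 (-3.19, SE 0.74), Hbb-bt (-2.75, SE 0.67) and Hba-a2 (-2.60, SE 0.68), and Alas2 (-2.62, SE 0.68), an enzyme of haem synthesis in red cells. Over all genes DESeq2 called these 5 in 15 against 05 (adjusted p between 0.00464 and 0.0194) and Hbb-bt in 10 against 05 (adjusted p = 0.0477). The list passed camera with the preset correlation (adjusted p = 5.25e-07 and 6.36e-09) but not with an estimated one (adjusted p = 0.69 for 10 against 05 and adjusted p = 0.15 for 15 against 05 with an estimated correlation). At time code 05, E3-05 1, E4-05 1 and E3-05 2 had 145 to 169 CPM of Hbb-bs, and without them the median in 15 against 05 was -1.02 and 0 of the 7 passed adjusted over the list alone.

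Genes of antigen presentation and of the interferon response were lower at time code 15 than at both earlier ones. Against time code 10, 17 of 17 antigen presentation genes were below 0 (median -0.33), and 6 fell when adjusted over the list alone. These were the class I gene H2-K1 (-0.45, SE 0.12), the related H2-Q4 (-0.50, SE 0.16), the class II genes H2-Aa (-1.14, SE 0.39), H2-Eb1 (-0.97, SE 0.32) and Cd74 (-0.94, SE 0.33), and the proteasome subunit Psmb9 (-0.65, SE 0.23). The list of lymphoid and plasma cell genes was lower at 15 than at 10 too, in 6 of 7 members (median -0.52; camera adjusted p = 0.0197, and adjusted p = 0.185 with an estimated correlation). That call ended without E3-10 2, E4-10 3, E3-15 1, E4-15 1 or E3-15 2, and whether class II genes fell in microglia or through fewer lymphoid cells stays open. Against time code 05, 15 of 17 were below 0 (median -0.37) and H2-K1 (-0.37, SE 0.12), H2-Q4 (-0.66, SE 0.16) and the peptide transporter Tap1 (-0.55, SE 0.14) fell when adjusted over the list alone. The interferon response list had 22 of 26 members below 0 against time code 10 (median -0.22) and 23 of 26 against 05 (median -0.18). Oasl2 (-0.59, SE 0.16) and Rsad2 (-0.71, SE 0.17), both induced by interferon, fell in 1 of these comparisons each when adjusted over the list alone. For antigen presentation camera gave adjusted p = 2.97e-10 and 8.04e-14, and adjusted p = 0.185 against 10 and adjusted p = 0.109 against 05 with an estimated correlation. For the interferon list it gave adjusted p = 4.84e-07 and 1.23e-07, and adjusted p = 0.185 and adjusted p = 0.15 with an estimated correlation. The antigen presentation and interferon lists kept their camera calls, and medians within 1.5 times, without each of the 16 libraries in turn. The list-alone calls of Tap1, Rsad2 and of H2-Q4 against 05 held as well, and that of H2-K1 against 05 ended without any 1 of 10 libraries. Against 10 all 7 list-alone calls ended without at least 5 libraries each, E3-10 1 and E3-15 4 among them for all 7. Leaving out single libraries cannot show what a block of adjacent columns carries. The antigen presentation list averaged 2.59 to 3.02 log2 CPM in the March libraries, 1.97 to 2.43 in those of April and 1.72 to 2.30 at time code 15. E4-10 3 (2.07) and E4-10 4 (1.97), of April, lay within the last range. For the interferon list these ranges were 1.91 to 2.32, 1.62 to 2.03 and 1.71 to 2.08. Over all genes edgeR called 0 members of these 2 lists, and DESeq2 called Rsad2 (adjusted p = 0.0384) and H2-Q4 (adjusted p = 0.0406) in 15 against 05. Time codes 05, 10 and 15 held 2, 3 and 3 hindbrain libraries. Camera with the preset correlation also called endothelial, choroid plexus, cytosolic ribosomal protein, and hypothalamus and pituitary genes in 15 against 10. All of these but the endothelial list were called against 05 too. None passed with an estimated correlation, and each call ended without at least 2 single libraries. The endothelial list averaged 5.27 log2 CPM in E3-10 and 5.09 in E4-10, against 5.09 in E3-15 and 5.10 in E4-15.

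Other glial and response genes also differed between time codes 15 and 05 when adjusted over their lists alone. Lcn2, a secreted protein of reactive astrocytes (-2.31, SE 0.54), and Clec7a, a receptor of activated microglia (-1.14, SE 0.29), fell, the latter not without E3-05 2. Genes of disease-associated microglia had 18 of 25 members below 0 (median -0.12; camera adjusted p = 0.0048, and adjusted p = 0.15 with an estimated correlation). Their call held without each of the 16 libraries in turn, but the median was -0.08 without E4-05 1, E4-05 3, E3-15 2 or E4-15 4 and -0.07 without E3-15 3. Complement genes had 14 of 15 below 0 (median -0.14; camera adjusted p = 0.00181, and adjusted p = 0.29 with an estimated correlation), a call that ended without E4-15 1 (-0.10); the median was -0.21 without E4-05 3 or E4-15 2 and -0.23 without E4-15 3. The reactive astrocyte list (11 of 14 below 0, median -0.06) passed camera with the preset correlation but not with an estimated one, and its call ended without any 1 of 8 libraries. The transcription factor Klf4 (0.95, SE 0.22), the NF-kB inhibitor Nfkbia (0.55, SE 0.13), the kinase Sgk1 (0.79, SE 0.19) and the clock repressor Ciart (0.47, SE 0.12) rose. Over all genes edgeR called 0 of these, and DESeq2 called Lcn2 (adjusted p = 0.00674), Klf4 (0.0241), Nfkbia (0.0439) and Sgk1 (0.0454). The rise of Sgk1, Klf4 and Nfkbia was not shared by all libraries of time code 15. Sgk1 was at 153 to 167 CPM in E3-15 2, E4-15 2 and E3-15 3, in adjacent columns, and at 77.9 to 93.8 CPM in E4-15 3, E3-15 4 and E4-15 4. In E3-15 1 and E4-15 1 it was at 57.2 and 55.9 CPM, within the 51.7 to 77.4 CPM of time code 05, and Klf4 and Nfkbia also lay within their time code 05 range there. The circadian clock list had 14 of 16 members above 0 (median 0.09, and 0.06 without E3-15 2; camera adjusted p = 0.000483, and adjusted p = 0.29 with an estimated correlation). Cholesterol synthesis genes had 22 of 24 members above 0 (median 0.08; camera adjusted p = 0.00105, and adjusted p = 0.591 with an estimated correlation). That call ended without E3-05 2, and the median was 0.05 without it, E4-15 2 or E4-15 3. In time code 10 against 05 they had 23 of 24 (median 0.13, and 0.04 without E3-10 1; camera adjusted p = 5.25e-07, and adjusted p = 0.69 with an estimated correlation). Immediate early genes had 16 of 20 members above 0 in time code 10 against 05 (median 0.37; camera adjusted p = 0.00054, and adjusted p = 0.992 with an estimated correlation). That call ended without E3-05 2 (median 0.22), E4-05 3 or E3-10 2 (0.05), and the median was 0.62 without E4-05 2. In that comparison Klf4 (0.82, SE 0.22) and Ciart (0.43, SE 0.12) rose when adjusted over their lists alone, calls that ended without any 1 of 9 libraries each. The pituitary genes Cga, Gh and Prl fell in time code 15 against both earlier ones when adjusted over the list alone, calls that ended without any 1 of 7 to 9 libraries, among them the Gh-rich E3-05 4 or E4-10 2. In time code 15 against 10, Rxra, the partner of the liver X receptors (-0.34, SE 0.09), and the chaperone Hspa5 (-0.23, SE 0.06) fell, and Sgk1 (0.72, SE 0.19) rose, each adjusted over its list alone; the call of Rxra ended without E3-10 1, E3-10 3, E4-15 1, E3-15 4 or E4-15 4.

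Over all 20437 genes, the time code comparisons gave 0 calls in edgeR and in limma-voom. In time code 15 against 05, Zfp36, which destabilises messenger RNA of cytokines (1.05, SE 0.17), and Apold1, an early response gene of endothelial cells (1.96, SE 0.36), had adjusted p = 0.0936 and 0.177. In all 458 genes had an unadjusted p under 0.05 and DESeq2 called 30 (16 higher and 14 lower, Zfp36 and Apold1 among the higher). Both genes rest on 2 sets of adjacent columns. At time code 15, Apold1 was at 28.8 to 32.1 CPM in E3-15 2, E4-15 2 and E3-15 3 and at 16.1 to 18.2 CPM in E4-15 3, E3-15 4 and E4-15 4, but at 7.21 and 4.04 CPM in E3-15 1 and E4-15 1. Zfp36 was at 12.2 to 20.3 CPM in those 6 and at 8.28 and 7.57 CPM in the last 2. The tests count 8 independent libraries per time code, and if libraries in adjacent columns share a source their p-values are too small. With the term for hindbrain libraries edgeR called 11 genes, 6 higher, among them Zfp36, Apold1 and the shear-responsive factor Klf2, and 5 lower, among them Lcn2 and Hba-a2. Without that term it called 3 genes when E4-15 1 was left out and 1 when E3-15 1 was left out. In time code 15 against 10, Ahnak, a large scaffold protein, differed by -0.55 (SE 0.09, adjusted p = 0.0885). Here 774 genes had an unadjusted p under 0.05, DESeq2 called 8 (2 higher and 6 lower) and edgeR called 2 without E4-10 4. In time code 10 against 05, TrnW differed by 0.60 (SE 0.11, adjusted p = 0.789), 320 genes had an unadjusted p under 0.05, and DESeq2 called 2, TrnW higher and Hbb-bt lower.

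Within E3 alone, time code 15 against 05 gave 0 genes in edgeR and limma-voom, 282 at an unadjusted p under 0.05 and 1 in DESeq2, LOC118568007. Lars2, a mitochondrial leucyl-tRNA synthetase, differed by 1.73 (SE 0.41), or 0.96 without E3-15 4 (234 CPM), and Zfp36 by 1.00 (SE 0.24). Within E4 alone edgeR, limma-voom and DESeq2 called 0 genes, with 546 at an unadjusted p under 0.05 in edgeR, and Zfp36 differed by 1.10 (SE 0.24). The titled months, compared within a time code with both E codes in each month, gave 0 genes in edgeR and limma-voom. For February against January, Capn11, a calpain protease, differed by -3.54 (SE 0.69), 345 genes had an unadjusted p under 0.05, and DESeq2 called 3, Capn11 lower and Gh and Prl higher. For April against March, Akap9, a scaffold of the Golgi and centrosome, differed by 0.67 (SE 0.11), 742 genes had an unadjusted p under 0.05, and DESeq2 called Akap9 alone. For June against May, Sdhaf2, an assembly factor of succinate dehydrogenase, differed by -0.43 (SE 0.09), 226 genes had an unadjusted p under 0.05, and DESeq2 called 0.

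All 24 libraries had the pattern of male tissue. Xist, the transcript of the inactive X chromosome, stayed at or below 0.178 CPM, and the Y-linked Ddx3y ran from 45.6 to 77.0 CPM, Uty from 15.4 to 27.4 CPM, Kdm5d from 19.4 to 33.4 CPM and Eif2s3y from 23.0 to 41.3 CPM.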

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

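The numbers of genes that differ between sets of 3 libraries, by adjacent column numbers or by shared number and E code, were tests set before those numbers were seen, although sharing within adjacent columns had been noticed in single genes; all other tests in this part were chosen after the result was seen.

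Of 180 groups of 4 libraries checked over 30 measures, 17 held a library that stood apart from the other 3 by Dixon's criterion, where chance sets apart about 1 in 20 groups, or 9. The cerebellum and hindbrain list set apart E3-05 2 (7.83 log2 CPM), E4-05 3 (7.52) and E4-10 2 (6.90), each the sole hindbrain library of its group. The same libraries were highest in their groups for Nr1h3, at 7.93 CPM in E3-05 2, 6.18 CPM in E4-05 3 and 5.72 CPM in E4-10 2. Homeostatic microglia genes were lowest in their groups in E3-05 2 (3.51 log2 CPM) and in E4-10 2 (3.61), and so were glutamatergic and GABAergic neuron genes in E3-05 2 (4.70 and 4.73).

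Hindbrain markers were high in 8 of the 24 libraries; 6 of the 6 labelled groups held both kinds of library, which argues against the labelled E code or time code as the source, and all 8 column numbers are multiples of 3 (chance 4.08e-06 for 8 libraries at a fixed interval of 3), so the library names may be out of step with the columns. Between the 8 sets of adjacent column numbers 100 genes differed with a hindbrain term, which missed the bound set beforehand, since 1 of 100 random divisions gave 201 (the next highest gave 14, and 75 gave 0). A guess that this division joined the 2 pituitary-rich libraries was wrong (201 among divisions that did not join them), and the count was read as undecided only after the division proved to join the 2 libraries with the highest thalamus means of the 16 (6.83 and 6.53 log2 CPM) and the next test was seen. Over 100 genes chosen without the hindbrain libraries, 6 of the 8 correlated best with the 2 libraries in the column numbers before them (mean r = 0.567 across genes, which are not independent replicates; exact permutation p = 7.44e-05), against 0 of the 8 with the libraries of their own number and E code (p = 0.977, exact permutation), and sets by number and E code differed in 0 genes. Of the 8 sets of adjacent columns 6 held 1 time code, against 0 of the 8 sets by number and E code. Neither the random divisions nor the permutations kept the time code, so a difference between time codes could also raise the match of adjacent columns. Time code alone would favour no pair among those of the same code. E3-05 2, E3-10 4, E3-15 3 and E4-15 4 correlated best with their own pair (r = 0.872, 0.604, 0.678 and 0.827), above another pair of their time code. For these libraries this argues against time code as the only source. E4-05 3 and E4-10 2 did not match their own pair best. Whether the adjacent columns share an animal, a dissection or a preparation stays open, since the labels name no animal and no region. Whether the names are at fault stays open too, and if they are wrong, the E4 and E3 groups are mixed.

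Blood genes were higher at time code 05, with a median log2 difference of -2.62 in 15 against 05. Blood left in the 3 libraries of column numbers 1 to 3 may account for most of it: without them the median was -1.02 and 0 of 7 genes passed adjusted over the list alone, though these libraries were picked for their blood genes, so some decrease was built into the test. The labelled time code cannot be told apart from this, since 4 of the 8 libraries of time code 05, those 3 and E4-05 3, lay above every library of time code 15 in the blood list and the other 4 did not. A difference in age or perfusion between time codes was not tested.

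Mural and fibroblast genes were lower in E4-10 than in E3-10, by 0.59 log2 CPM in the list mean, with E3-10 the highest and E4-10 the lowest of the 6 groups. An unequal share of hindbrain libraries is argued against by the median of -0.66 with a hindbrain term, against -0.73 without. A varying amount of meninges and vessels in the dissected tissue stays a candidate explanation. The list mean ranged over 0.61 within the 4 libraries of E4-15, the largest range in the other 4 groups and slightly more than the difference between the groups. The largest range of single libraries tends to exceed the spread of a difference between 2 means, so this comparison cannot decide. The E code at time code 10 stays open too and was not tested apart from the amount of meninges and vessels.

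Other libraries that stood apart were E4-15 3 with the lowest total count of its group (41.5 M counts) and Apoe highest in E3-05 3 (1203 CPM). Within their groups of 4, Asxl1 was highest in E4-15 2 (64.2 CPM) and Kmt2a lowest in E4-10 4 (173 CPM). Also within their groups, endothelial genes were lowest in E4-15 2 (4.97 log2 CPM), ependymal genes highest in E4-15 1 (1.69 log2 CPM) and olfactory bulb genes lowest in E3-10 3 (1.20 log2 CPM).

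Other splits of the samples say nothing about chance for the 13 counts of 0 genes, since every split gives at least 0. Over all 35 splits of the 8 libraries the highest other counts were 0, 8 and 4 for E4 against E3 at time codes 05, 10 and 15, and 0 for time code 15 against 05 within E3 and within E4. Over 30 drawn splits they were 1 for E4 against E3 averaged, 0, 1 and 0 for time codes 10 against 05, 15 against 10 and 15 against 05, and 1 for the interaction. The titled months allow 18 splits, too few for a share under 0.05; the real count was 0 for each, and the highest other count was 0 for February against January, 3 for April against March and 0 for June against May.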

How the results depend on the processing

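The hindbrain term and the settings that leave out the hindbrain, blood-rich or pituitary-rich libraries, and terms for the sets of adjacent columns, were chosen after the data were seen. Of 142 counts of genes under alternatives set in advance, other than leaving out single libraries, 132 stayed at 0. The other 10 were 8 of DESeq2 (14 at time code 10 for E4 against E3, 2 for time code 10 against 05, 8 for 15 against 10, 30 for 15 against 05, 1 for 15 against 05 in E3, 7 for the interaction, 3 for February against January and 1 for April against March), 1 with the replicate block (Zfp36 in 15 against 05, adjusted p = 0.0346) and 1 with only the libraries compared (15 against 10). With the hindbrain term the counts were 2 for E4 against E3 at time code 10, 1 for 15 against 10, 11 for 15 against 05, 1 for the interaction and 1 for April against March. Leaving out single libraries gave 0 to 2 genes for 15 against 10 (2 without E4-10 4), 0 to 3 for 15 against 05 (1 without E3-15 1 and 3 without E4-15 1), and 0 to 0 for the others. Without the 8 hindbrain, the 3 blood-rich or the 2 pituitary-rich libraries all 13 counts stayed at 0. The 168 named gene values kept their side of the threshold and their direction to within 1 SE in 4061 of 4120 alternative values; 29 passed the threshold and 30 changed sign by over 1 SE. As edgeR called 0 genes, no call could be lost, and the 4061 values are of genes that stayed uncalled.

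The lists called by camera depended on the correlation. With an estimated correlation, with fry, and with the hindbrain term and an estimated correlation together, 1 list was called for E4 against E3 at time code 10 and 0 in the other 6 comparisons. With the hindbrain term 2 lists were called for E4 against E3 at time code 05 and 12 for time code 15 against 10. With terms for the sets of adjacent columns and the hindbrain libraries, the E4 against E3 comparisons and the interaction gave 0 genes each, and 8 lists were called at time code 05, 13 at 10, 6 at 15 and 3 averaged. With an estimated correlation as well these were 0 each, and the mural and fibroblast list at time code 10 had adjusted p = 0.0749. Without the 8 hindbrain libraries 4 were called at time code 05, 0 at 15 and 7 averaged, and without the 3 blood-rich libraries 10 at time code 05. The blood list in 15 against 05 had adjusted p = 0.15 with an estimated correlation, 0.307 with fry, 0.0931 with the hindbrain term and an estimated correlation and 0.0825 without the 3 blood-rich libraries; the antigen presentation list had 0.109, 0.27 and 0.0931 under the first 3 of these. Leaving out single libraries, E4 against E3 at time code 05 (1 list in full) gave 0 to 8: 2 without E3-05 1, 4 without E4-05 1, 8 without E3-05 2, E4-05 2 or E3-05 3, 5 without E4-05 3 or E3-05 4, and 0 without E4-05 4. At time code 10 (16 in full) it gave 8 to 19, with 8 without E3-10 1. At time code 15 (8 in full) it gave 1 to 9: 3 without E3-15 1, 5 without E3-15 4 and 1 without E4-15 4. Averaged (15 in full) it gave 4 to 18: 4 without E3-05 3 or E4-15 4, 5 without E3-10 1, 6 without E4-15 2, 7 without E3-05 2, E4-05 2, E4-05 3 or E4-10 3, 8 without E4-10 4 or E4-15 1, and 9 without E3-10 2, E3-15 1 or E3-15 3. Time code 10 against 05 (4 in full) gave 3 to 8: 7 without E4-05 3 or E4-10 4 and 8 without E3-10 4. Time code 15 against 10 (7 in full) gave 2 to 14: 2 without E3-10 2, 4 without E4-10 3, 11 without E3-10 4 or E3-15 4, and 14 without E4-10 2. Time code 15 against 05 (11 in full) gave 7 to 16, with 7 without E4-05 1. Where a count moved for another reason than fewer samples or a different test, the cause was not tested. Not run were a sex covariate (all 24 libraries had the male pattern), titled month as a covariate between time codes, and the replicate block for the months, which could not be estimated. Of the 16 lists called at time code 10 for E4 against E3, 5 held their call without each single library, against 0 of 1 at time code 05, 0 of 8 at 15 and 0 of 15 averaged. For time codes 10 against 05, 15 against 10 and 15 against 05 these numbers were 2 of 4, 2 of 7 and 5 of 11. The spread between libraries was a coefficient of variation of 40.8%, and of 22.5% with the hindbrain term; whether depth limited the tests was not tested.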

Other observations

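The single genes given in this part were chosen after their values were seen. Some genes followed the sets of 3 adjacent column numbers across E codes. Ide, the insulin-degrading enzyme, lay between 50.6 and 75.3 CPM in the 9 libraries of column numbers 1 to 6 and 19 to 21, and between 84.8 and 166 CPM in the other 15. Sgk1 lay between 153 and 167 CPM in column numbers 19 to 21 (E3-15 2, E4-15 2 and E3-15 3) and between 51.7 and 93.8 CPM in the other 21 libraries. In the same 3 libraries Apold1 lay between 28.8 and 32.1 CPM, against 18.2 CPM or less elsewhere. Klf2 did not separate them, at 26.8 to 34.4 CPM there and up to 34.5 CPM elsewhere.

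Zfp36 lay between 16.2 and 20.3 CPM in column numbers 22 to 24, 12.2 and 14.1 CPM in 19 to 21, and at 10.0 CPM or less in the other 18 libraries. Choroid plexus transcripts varied widely within a group: Ttr, the thyroid hormone carrier of that tissue, ran from 3.54 CPM in E4-05 1 to 2580 CPM in E4-05 3. The closest pair of libraries by log2 CPM was E3-10 4 and E3-05 2, both hindbrain libraries, with r = 0.989 across genes; their counts differed by a chi-square of 19.8 per degree of freedom, so they are not the same library counted again.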
